A study of Malus domestica with 18 samples.

How the data were processed

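Poly(A) RNA of 18 libraries from apple shoot explants was sequenced, with 3 libraries for each of 3 media at 2 times. Per the labels, replicates are biological, but the labels do not say whether they came from separate cultures or vessels, so the tests measure only the spread between samples. The deposited count table holds whole-number counts of fragments per gene, and per the submitters' processing notes reads were called with CASAVA, aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. The genome build and strand setting are not given in the sources used here, so no positions are printed. The deposited FPKM table holds the same genes and libraries and was not used here. Libraries were mapped to groups from the labels alone. The labels do not say what the letter b marks in 4 library names that otherwise repeat the name of replicate 1.

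Gene names are the best Swiss-Prot match in the deposited table, present for 27453 of 42841 genes (64.1%), so a name gives the protein family, and reads of close paralogs may be shared. Gene identifiers matched 0 entries of the reference gene table. Gene lists, 46 in all, were drawn from protein names, and 151 names that matched by accident were dropped from 11 lists after the table was read and before genes were tested. Plastid-encoded and mitochondrion-encoded lists were added later, by protein name and not by genome location, so a member may be a nuclear copy.

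Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, R 4.3.3) in 1 fit of all 18 libraries with 6 groups, which remained the leading analysis although it called 0 genes at 48 hour. filterByExpr (minimum count 10, minimum total 15) left 26053 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The 9 comparisons were each cytokinin against control and TDZ against BAR at both times, the controls over time, and the interaction of each cytokinin with time. Intervals are 95% and cover the spread in the fit. Gene lists were tested with camera in limma 3.58.1 against all other genes, with a preset correlation of 0.01 and with an estimated one, and with fry. With the estimated correlation 1 of 128 list calls was kept in the fit of all 18 libraries. By fry no list passed for TDZ or BAR against control at 48 hour, while some did at 4 week. Where a group had no count, the fold is given as at least the ratio to 3 counts over that group.

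Named genes were picked by a rule written before the files were read: the 8 highest and 8 lowest fold changes among called genes with at least 5 CPM in the higher group, up to 4 list members of smallest p, and the 3 most abundant type-A regulators and cytokinin oxidases. For the fold changes, the 3 libraries of the higher group all had to lie above the 3 of the lower group. Genes without a characterised protein name were left out of that part. Since no gene was called at 48 hour, the first part was also applied, after that result was seen, to an edgeR fit of the 9 libraries of the same time.

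Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter, a 2-fold threshold, the groups compared alone, each library left out in turn, libraries whose names end in b summed with their namesakes, and the replicate number as a block. Libraries held 12546489 to 21279097 counts. The common dispersion was 0.185 over all libraries, 0.126 at 48 hour, 0.239 at 4 week and 0.117 at 4 week without the library labelled TDZ, 4 week, replicate 3. The scripts were tested on simulated data with 200 changed genes. For TDZ against control at 48 hour the fit of all libraries recovered 0%, 8%, 46% and 70% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, with 4 false calls, and the 48 hour libraries 2%, 4%, 52% and 74%, with 5 false calls. For TDZ against control at 4 week the shares were 0%, 4%, 40% and 58%, with 2 false calls. Apart from the changed genes, each simulated gene had the same mean level in all libraries, and no library stood apart. The shares and false calls therefore do not carry over the differences over time or the unlike library on TDZ at 4 week.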

Results

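RNA was sequenced from in vitro shoot explants of apple (Malus domestica, cultivar Húsvéti rozmaring) that had been cut to 20 mm and placed on medium with or without a cytokinin, a plant hormone that promotes cell division and shoot formation. Thidiazuron (TDZ) is a synthetic phenylurea with cytokinin activity. 6-benzylaminopurine riboside (BAR) is the riboside of an adenine-type cytokinin. Both were used at 4.5 µM, and the control medium held no cytokinin. Every medium also held 0.49 µM indole butyric acid and 0.58 µM gibberellic acid, and the explants came from shoots kept without cytokinin beforehand. Axillary shoots were collected after 48 hour and after 4 week, with 3 libraries for each of the 6 combinations of medium and time. The 18 libraries held 12546489 (TDZ, 48 hour, replicate 1) to 21279097 (control, 4 week, replicate 1) counted fragments. Of the genes in the table, 26053 of 42841 had enough counts to be tested. Levels are counts scaled to library size (CPM), given as mean ± SD over 3 libraries unless stated, and fold changes are log2 values with their standard error (SE).

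Time separated the libraries on each medium, and at 4 week medium did so as well, except for 1 library. The first principal component held 52.6% of the variance and the second 16%. At 48 hour the 9 libraries lay close together and media overlapped, control replicate 1 correlating at 0.977 with BAR replicate 3 and at 0.969 with control replicate 3, with Spearman correlations across genes of 0.941 to 0.968 within the TDZ group and 0.947 to 0.972 within the BAR group. At 4 week the libraries labelled TDZ, replicates 1 and 2, correlated at 0.974 with each other, but at 0.807 and 0.803 with the library labelled TDZ, 4 week, replicate 3. That library correlated at 0.944, 0.946 and 0.947 with the 3 controls of 4 week. Cytokinin dehydrogenase 3 (DVH24_029452), an enzyme that degrades cytokinins and whose gene is switched on by them, stood at 212 and 182 CPM in replicates 1 and 2 and at 0.0644 CPM in replicate 3. Over the 10 type-A response regulators, which are early cytokinin response genes, the median log2 ratio to the 4 week controls was 4.00, 3.95 and 0.08 in replicates 1, 2 and 3. The name of this library ends in b and otherwise repeats that of replicate 1, as do those of the third replicates of control at 48 hour and of BAR at both times. The labels call all of them biological replicates, but if these 4 are repeats of the same explants, their groups hold 2 independent samples and not 3. Counts of the paired names differed by a chi-square per degree of freedom of 31.8 (23.5 and 21 for the other pairs of the group) in the control at 48 hour, 72.9 (52.8 and 28.9) on BAR at 48 hour and 265 (35.1 and 268) on TDZ at 4 week. Only on BAR at 4 week was the pair the closest of its group, at 16.7 (41.3 and 45.7). Every mean for TDZ at 4 week below includes this library, and its SD is correspondingly wide. Control, 4 week, replicate 1 also stood apart, at 0.927 and 0.931 against replicates 2 and 3, which correlated at 0.987.

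**Figure D1:**
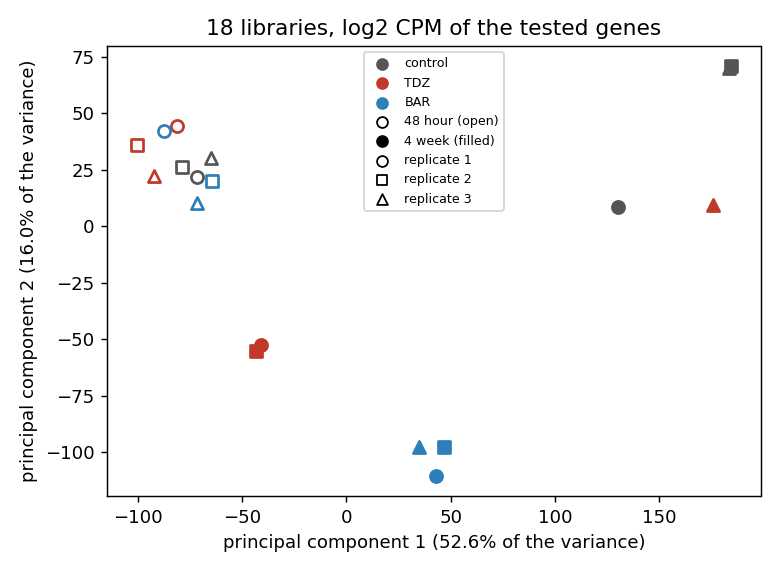
The 18 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; each point is 1 library, colour gives the medium, open symbols are 48 hour, filled symbols are 4 week, and the symbol shape gives the replicate. The filled triangle of the library labelled TDZ, 4 week, replicate 3 lies with the 4 week controls, with which it correlated at 0.944 to 0.947.

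The first question was how explants responded to TDZ within 48 hour. Genes of cytokinin degradation and cytokinin feedback stood far above the control. Cytokinin dehydrogenase 3 (DVH24_029452) averaged 306 ± 121 CPM on TDZ and 1.99 ± 1.59 CPM in the control, and cytokinin dehydrogenase 5 (DVH24_012939) 155 ± 24.7 and 7.91 ± 4.4 CPM. Among type-A response regulators, ARR17 (DVH24_024436) averaged 41.5 ± 5.82 and 3.19 ± 0.786 CPM, ORR4 (DVH24_042790) 13.1 ± 1.78 and 0.878 ± 0.0766 CPM, and the abundant ARR3 (DVH24_007079) 164 ± 19.5 and 35.3 ± 17.6 CPM. All 10 type-A regulators had positive fold changes, with a median of 1.94, and as a list they rose against all other genes (camera adjusted p = 2.8e-11, but adjusted p = 0.26 with an estimated correlation). The 9 cytokinin oxidases tested rose as a list too (adjusted p = 2.6e-06, and adjusted p = 0.038 with an estimated correlation). By fry neither list passed (adjusted p = 0.24 for type-A regulators and 0.059 for oxidases), nor did any other list. In fits chosen after the results were seen, the camera adjusted p with an estimated correlation differed. Without the library labelled TDZ, 4 week, replicate 3, it was 6.7e-05 for type-A regulators and 0.0032 for oxidases. In the 48 hour libraries alone it was 0.0059 and 0.064. Adjusted over the list alone, 4 of the 10 type-A regulators and 4 of the 9 oxidases were higher. Another abundant oxidase, cytokinin dehydrogenase 7 (DVH24_020512), averaged 20.9 ± 6.41 CPM on TDZ and 18.8 ± 3.03 CPM in the control, an uncalled difference whose sign turned without TDZ, 48 hour, replicate 1 (log2 fold change -0.13).

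Other genes stood higher on TDZ at 48 hour as well. (-)-alpha-pinene synthase (DVH24_003515), which makes a volatile terpene, averaged 5.63 ± 4.17 against 0.0447 ± 0.0775 CPM, and sieve element occlusion B (DVH24_040938), a phloem protein, 385 ± 359 against 29.5 ± 3.22 CPM. (R)-mandelonitrile lyase 3 (DVH24_002314), of a family that breaks down cyanogenic compounds, averaged 87.6 ± 27.3 against 7.36 ± 0.896 CPM. Cyclin-D3-1 (DVH24_021694), which promotes entry into the cell cycle, averaged 201 ± 31 against 76.1 ± 10.2 CPM. A cytokinin receptor, histidine kinase 4 (DVH24_007629), averaged 79.2 ± 0.768 against 36.2 ± 5.16 CPM. Lower on TDZ stood metallothionein-like protein type 2 (DVH24_032849) at 47.4 ± 17.7 against 292 ± 25.3 CPM. So did NADP-dependent D-sorbitol-6-phosphate dehydrogenase (DVH24_021353), an enzyme of sorbitol synthesis, at 7.24 ± 4.69 against 69.5 ± 34.8 CPM. Nicotianamine synthase (DVH24_036506), which makes a metal chelator, stood at 8.18 ± 4.46 against 59.4 ± 16.5 CPM. Several lists fell as groups by camera with the preset correlation, but none of them passed by fry. The 86 WRKY factors, regulators of defence and senescence genes, had a median log2 fold change of -0.30 (adjusted p = 5.6e-07, adjusted p = 0.17 with an estimated correlation). Flavonoid and anthocyanin synthesis had a median of -0.51 (adjusted p = 8.6e-05, adjusted p = 0.44 with an estimated correlation). Nitrate uptake and assimilation had one of -0.43 (adjusted p = 9.8e-05, adjusted p = 0.3 with an estimated correlation). Terpene synthesis had a median of -0.73 (adjusted p = 9.8e-05, adjusted p = 0.38 with an estimated correlation). Expansins and xyloglucan endotransglucosylases, which loosen cell walls, had one of -0.33 (adjusted p = 0.00043, adjusted p = 0.38 with an estimated correlation). Ribosomal protein genes rose slightly, with a median of 0.19 over 244 genes (adjusted p = 1.9e-08, adjusted p = 0.72 with an estimated correlation).

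In the edgeR quasi-likelihood fit of all 18 libraries no single gene passed the adjusted threshold for TDZ against control at 48 hour, with 1439 genes at an unadjusted p under 0.05. Limma-voom also called 0 genes and DESeq2 called 29 higher and 74 lower. A fit of the 9 libraries of 48 hour alone, added after that result was seen, called 46 higher and 45 lower genes, among them every gene given for TDZ at 48 hour above except cytokinin dehydrogenase 7, with adjusted p = 0.00028 for cytokinin dehydrogenase 3 (DVH24_029452) and adjusted p = 9.2e-05 for ARR17 (DVH24_024436). Many of these genes were picked because this same fit called them, so their passing in it lends them no further weight. Leaving out the library labelled TDZ, 4 week, replicate 3, from the fit of all libraries gave 12 higher and 13 lower genes.

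BAR at 48 hour stood above the control in several of the same cytokinin genes. Cytokinin dehydrogenase 3 (DVH24_029452) averaged 32.9 ± 10.8 CPM against 1.99 ± 1.59 CPM in the control, ORR4 (DVH24_042790) 8.01 ± 1.82 against 0.878 ± 0.0766 CPM, ARR17 (DVH24_024436) 11.6 ± 2.38 against 3.19 ± 0.786 CPM, and (R)-mandelonitrile lyase 3 (DVH24_002314) 42.6 ± 13.2 against 7.36 ± 0.896 CPM. All 10 type-A regulators had positive fold changes with a median of 1.26, and the list rose (adjusted p = 1.5e-08, adjusted p = 0.3 with an estimated correlation). So did the cytokinin oxidases, with a median of 1.18 (adjusted p = 2e-05, adjusted p = 0.062 with an estimated correlation). By fry neither list passed (adjusted p = 0.67 for type-A regulators and 0.28 for oxidases), nor did any other list. The camera adjusted p with an estimated correlation depended on the fit. Without the library labelled TDZ, 4 week, replicate 3, it was 0.00024 for type-A regulators and 0.0088 for oxidases. In the 48 hour libraries alone it was 0.0084 and 0.094. Adjusted over the list alone, 4 oxidases and 0 type-A regulators were higher. Jasmonate synthesis genes and their JAZ repressors rose as a list, 34 of 42 with positive fold changes and a median of 0.43 (adjusted p = 8.3e-05, adjusted p = 0.22 with an estimated correlation). Secondary wall and lignin genes rose too, with a median of 0.45 over 81 (adjusted p = 0.0013, adjusted p = 0.44 with an estimated correlation). Phloem markers rose as a list, with a median of 0.24 over 31 (adjusted p = 0.0055, adjusted p = 0.24 with an estimated correlation). The 4 cytokinin response factors had a median of 0.80 (adjusted p = 0.0036, adjusted p = 0.22 with an estimated correlation).

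Plastid-encoded transcripts stood lower on BAR at 48 hour. Of 41 such genes 39 had negative fold changes, with a median of -1.64. Photosystem II CP47 (DVH24_037513) averaged 84.9 ± 20.5 against 324 ± 38.7 CPM, photosystem II protein H (DVH24_037512) 20.3 ± 6.47 against 105 ± 10.9 CPM, and the ATP synthase beta subunit (DVH24_034244) 33.7 ± 12 against 204 ± 32.9 CPM. The list of light harvesting and photosystem proteins, 14 of whose 80 members are plastid-encoded, fell (adjusted p = 0.00083, adjusted p = 0.96 with an estimated correlation), and its 66 nuclear members had a median of -0.07. The edgeR fit of all libraries called 0 genes for BAR at 48 hour, with 693 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 2 higher and 3 lower. The fit of the 48 hour libraries called 5 higher and 4 lower genes, which include the named genes of the 3 plastid proteins (adjusted p = 0.028 for the beta subunit, DVH24_034244), and the fit without the library labelled TDZ, 4 week, replicate 3, called 1 gene. Those 3 were picked from the calls of the 48 hour fit, so their passing in it lends them no further weight.

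A direct comparison of the cytokinins at 48 hour, at the same concentration, put TDZ above BAR for both leading oxidases. Cytokinin dehydrogenase 3 (DVH24_029452) was 306 ± 121 CPM on TDZ and 32.9 ± 10.8 CPM on BAR, a log2 difference of 3.22 ± 1.26 (SE), and cytokinin dehydrogenase 5 (DVH24_012939) was 155 ± 24.7 and 36.6 ± 5.68 CPM, a difference of 2.08 ± 0.78. In the fit of the 48 hour libraries both had adjusted p = 0.046. Among type-A regulators ARR17 (DVH24_024436) averaged 41.5 ± 5.82 and 11.6 ± 2.38 CPM, a log2 difference of 1.84 ± 0.59 (adjusted p = 0.47, and 0.025 in the fit of the 48 hour libraries). No difference was detected for 2 others: ARR6 (DVH24_008781) averaged 87.8 ± 7.3 and 75.2 ± 12.8 CPM, a log2 difference of 0.23 with a 95% interval from -1.53 to 1.98, and ARR3 (DVH24_007079) had a difference of 0.68 with an interval from -0.72 to 2.08. The blue-light receptor Adagio protein 3 (DVH24_007611), part of the circadian clock list, averaged 47.2 ± 14.7 and 8.73 ± 1.7 CPM, while the clock-related factor REVEILLE 7 (DVH24_009191) averaged 27.8 ± 3.63 and 70.8 ± 4.01 CPM. The circadian list of 27 genes did not pass as a whole (adjusted p = 0.45). Lower on TDZ than on BAR stood delta-1-pyrroline-5-carboxylate synthase (DVH24_004376), which makes proline, at 1.37 ± 0.403 and 11.6 ± 1.67 CPM, and nicotianamine synthase (DVH24_036506) at 8.18 ± 4.46 and 91.1 ± 60 CPM. WRKY factors were lower as a list (median -0.48, adjusted p = 4.2e-08, adjusted p = 0.18 with an estimated correlation). So were secondary wall and lignin genes (median -0.45, adjusted p = 4.2e-05, adjusted p = 0.41 with an estimated correlation). Ribosomal proteins were higher (median 0.23, adjusted p = 6.8e-10, adjusted p = 0.5 with an estimated correlation). No gene passed in the edgeR fit of all libraries, with 1970 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 31 higher and 120 lower. The 48 hour fit called 11 higher and 18 lower genes, the fit without the library labelled TDZ, 4 week, replicate 3, called 5, and the fit without control, 48 hour, replicate 3, called 1.

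**Figure D2:**
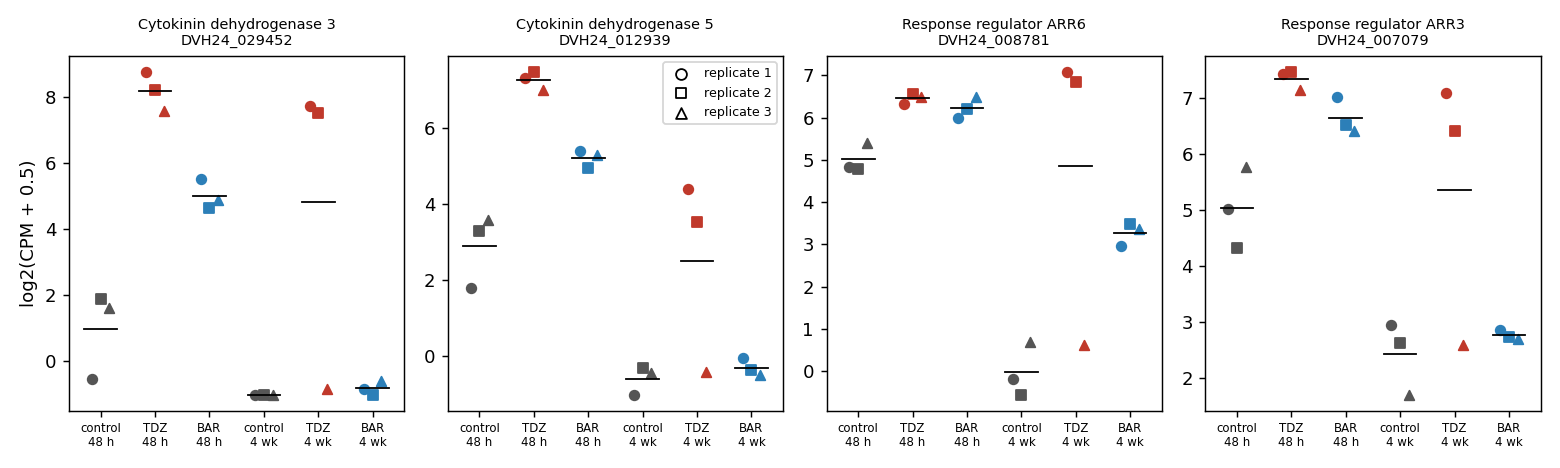
log2(CPM + 0.5) of 2 cytokinin dehydrogenase genes and 2 type-A response regulator genes in each of the 18 libraries; colour gives the medium, symbol shape the replicate, and the black line is the mean of the 3 libraries of a group on this scale. Cytokinin dehydrogenase 3 (DVH24_029452) stood at 306 CPM on TDZ and 32.9 CPM on BAR at 48 hour, and at 4 week it was high in the libraries labelled TDZ, replicates 1 and 2, only.

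After 4 week on TDZ, cytokinin response, cell division and wall genes were higher than in the control, and heat shock genes and plastid-encoded transcripts were lower. For TDZ and BAR against control, rose and fell mean higher and lower than in the control of the same time. Of the 10 type-A regulators 9 rose and 0 fell, also when adjusted over the list alone (list adjusted p = 5.2e-05, adjusted p = 0.52 with an estimated correlation). ARR6 (DVH24_008781) averaged 83.4 ± 72.1 CPM against 0.559 ± 0.49 CPM, a log2 fold change of 7.29 ± 1.16 (SE, adjusted p = 0.002), and ARR3 (DVH24_007079) 75.8 ± 66 against 5.24 ± 2.27 CPM (adjusted p = 0.0034). Cytokinin dehydrogenase 3 (DVH24_029452) averaged 131 ± 115 CPM and had no count in the 3 controls, at least 2070-fold higher against a floor of 3 counts over the group. Among the 9 cytokinin oxidases 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.59, adjusted p = 0.79 with an estimated correlation). The one that fell, cytokinin dehydrogenase 7 (DVH24_020512), averaged 29.4 ± 2.9 against 65.6 ± 19.7 CPM. In the cell cycle list 34 of 78 rose and 0 fell (adjusted p = 1.9e-05, adjusted p = 0.52 with an estimated correlation), with Cyclin-D3-1 (DVH24_021694) at 45.7 ± 39.2 against 4.73 ± 2.06 CPM and Cyclin-D1-1 (DVH24_034392) at 7.03 ± 6.14 against 0.0893 ± 0.0813 CPM. DNA replication and histone genes rose in 40 of 110 cases and fell in 0 (adjusted p = 5.7e-05, adjusted p = 0.55 with an estimated correlation). Histone H2A.1 (DVH24_036599) averaged 41.9 ± 36.2 against 0.235 ± 0.281 CPM, and the licensing factor MCM2 (DVH24_041154) 11.2 ± 9.94 against 0.407 ± 0.167 CPM.

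Meristem, auxin and wall genes moved with them. Of 53 shoot meristem regulators 27 rose and 3 fell (adjusted p = 0.0026, adjusted p = 0.57 with an estimated correlation). WUSCHEL-related homeobox 4 (DVH24_012479), a regulator of vascular stem cells, averaged 5.01 ± 4.96 against 0.0364 ± 0.063 CPM, and knotted-1-like 1 (DVH24_039627) 6.17 ± 5.25 CPM against no count, at least 97.5-fold higher. Knotted-1-like 3 (DVH24_021147) fell from 301 ± 98.5 CPM in the control to 92.9 ± 21.5 CPM. Of 33 Aux/IAA proteins, the repressors of auxin signalling, 18 rose and 0 fell (adjusted p = 2.8e-05, adjusted p = 0.52 with an estimated correlation). Of 99 pectin remodelling genes 38 rose and 2 fell (adjusted p = 0.00015, adjusted p = 0.52 with an estimated correlation), such as pectate lyase 18 (DVH24_039717) at 73.2 ± 63.1 against 0.324 ± 0.327 CPM, and pectate lyase 5 (DVH24_033738) at 41.5 ± 39 CPM against no count, at least 657-fold higher. Of 81 secondary wall genes 33 rose and 2 fell (adjusted p = 0.0018, adjusted p = 0.52 with an estimated correlation), and the abundant cellulose synthase subunit 7 (DVH24_017596) fell from 1090 ± 759 to 92 ± 56.2 CPM. Of 41 terpene and triterpene genes 14 rose and 0 fell (adjusted p = 2.2e-05, adjusted p = 0.52 with an estimated correlation), cycloartenol synthase 2 (DVH24_018731) among them at 62.6 ± 45.9 against 7.05 ± 4 CPM. The GDSL lipase LTL1 (DVH24_036863) at 103 ± 89.4 CPM and gibberellin-regulated protein 6 (DVH24_037114) at 40.2 ± 35.5 CPM had no count in the controls, at least 1640-fold and 635-fold higher. The 48 hour controls held 256 ± 55.6 CPM of LTL1, 112 ± 14.1 CPM of gibberellin-regulated protein 6 and 84.1 ± 6.96 CPM of pectate lyase 5 (DVH24_033738). For these genes the difference at 4 week goes with a loss in the control and not with a rise on TDZ over time. The rule for named genes kept as higher only genes whose 3 TDZ libraries all lay above the 3 controls. Since the library labelled TDZ, 4 week, replicate 3, lay with the controls, this rule favoured genes with no count in the controls. The lack of control counts among the genes picked by fold change is therefore partly set by the rule. The pectin and terpene lists passed on BAR at 4 week too. Pectin remodelling genes rose there in 31 of 99 cases and fell in 10 (adjusted p = 0.0096, 0.61 with an estimated correlation). Terpene and triterpene genes rose in 12 of 41 and fell in 1 (adjusted p = 0.043, 0.61 with an estimated correlation).

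Heat shock genes fell in 30 of 90 cases and rose in 6 (adjusted p = 5.7e-06, adjusted p = 0.52 with an estimated correlation). Heat stress factor B-2a (DVH24_001245) fell from 44.8 ± 28.2 to 3.99 ± 2.24 CPM, and B-4 (DVH24_020704) rose from no count to 8.46 ± 7.39 CPM, at least 134-fold. The rule for named genes kept as lower only genes whose 3 TDZ libraries all lay below the 3 controls. The 8 genes of lowest fold change that it left are all plastid-encoded by name, such as photosystem II D2 (DVH24_034793) at 14.5 ± 6.93 against 1200 ± 1020 CPM. For 1 of them, an ATP synthase subunit a gene (DVH24_033683), the location in the deposited table leaves a nuclear copy possible. That control mean spans 39.9, 1970 and 1590 CPM in replicates 1, 2 and 3. Genes at control level in the library labelled TDZ, 4 week, replicate 3, were passed over by the rule. The sugar transporter SWEET15 (DVH24_041082) stood at 0.181, 0.084 and 560 CPM on TDZ and at 315, 933 and 969 CPM in the controls. Of the 66 nuclear light harvesting and photosystem genes 11 fell and 1 rose, with a median of -0.55, and in the 4 week libraries alone 1 fell and 0 rose.

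In all, 4388 genes rose and 2532 fell on TDZ at 4 week, where the median gene lay at 0.14 on the log2 scale. The total of 6920 depended on the libraries and on the fit: it was 10828 without the library labelled TDZ, 4 week, replicate 3, 3373 and 3506 without replicates 1 and 2, and 3870 and 3835 without control, 4 week, replicates 2 and 3. Limma-voom called 1879 higher and 2692 lower genes, the 9 libraries of 4 week alone 782 and 676, and a fit of the 6 libraries compared called 0, which ended the call of each of the 56 genes followed for this comparison. Limma-voom ended 33 of these calls and the 4 week libraries alone 19. In the 4 week libraries alone type-A regulators rose in 3 of 10 cases, cell cycle genes in 5 of 78, DNA replication and histone genes in 3 of 110 and Aux/IAA proteins in 1 of 33, and heat shock genes fell in 12 of 90.

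After 4 week on BAR auxin response genes were higher than in the control, and neither type-A regulators nor cytokinin oxidases passed as a list. Of the 10 type-A regulators 2 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.43, adjusted p = 0.83 with an estimated correlation). Of all 26053 genes tested 4481 rose and 3319 fell. ARR6 (DVH24_008781) averaged 9.31 ± 1.76 against 0.559 ± 0.49 CPM (adjusted p = 0.0099; not called by limma-voom, log2 fold change 4.38, nor in the 4 week libraries alone, 4.04). ARR9 (DVH24_019719) 5.19 ± 0.384 against 0.511 ± 0.471 CPM (adjusted p = 0.021). That call was lost without control, 4 week, replicate 2 (log2 fold change 3.34) or 3 (2.74), by limma-voom (4.04) and in the 4 week libraries alone (3.20). ARR3 (DVH24_007079) averaged 6.33 ± 0.384 and 5.24 ± 2.27 CPM, an uncalled difference whose sign turned without control, 4 week, replicate 3 (log2 fold change -0.03). Of the 9 cytokinin oxidases 3 fell and 0 rose, also adjusted over the list alone, but the list median was 0.27 (list adjusted p = 0.17, adjusted p = 0.55 with an estimated correlation). Cytokinin dehydrogenase 7 (DVH24_012708) fell from 39.1 ± 4.87 to 3.49 ± 2.12 CPM, another dehydrogenase 7 (DVH24_020512) from 65.6 ± 19.7 to 28 ± 9.38 CPM, and a dehydrogenase 5 (DVH24_020176) from 8.79 ± 3.98 to 0.66 ± 0.37 CPM. Of 33 Aux/IAA proteins 20 rose and 0 fell (adjusted p = 3e-07, adjusted p = 0.51 with an estimated correlation), AUX28 (DVH24_021779) from 1.62 ± 0.675 to 164 ± 48.2 CPM. Of 27 SAUR proteins, small auxin-induced regulators of growth, 15 rose and 2 fell (adjusted p = 0.0031, adjusted p = 0.51 with an estimated correlation), SAUR78 (DVH24_000504) from 17.7 ± 18.9 to 262 ± 76.5 CPM. Expansins and xyloglucan enzymes rose in 23 of 56 cases and fell in 5 (adjusted p = 0.011, adjusted p = 0.51 with an estimated correlation), Expansin-A8 (DVH24_022849) from 11.3 ± 2.59 to 130 ± 11.4 CPM. Flowering regulators rose in 20 of 75 cases and fell in 1 (adjusted p = 0.0068, adjusted p = 0.51 with an estimated correlation), with APETALA 2 (DVH24_030086) at 69.7 ± 6.99 against 18.8 ± 2.38 CPM and squamosa promoter-binding-like 14 (DVH24_005100), which belongs to a family that marks the adult growth phase, at 51.6 ± 3.81 against 8.4 ± 1.46 CPM. Some of these lists passed on TDZ at 4 week too. SAUR proteins rose there in 11 of 27 cases and fell in 2 (adjusted p = 0.034, 0.57 with an estimated correlation). Expansins and xyloglucan enzymes rose in 24 of 56 and fell in 1 (adjusted p = 0.016, 0.52 with an estimated correlation). Flowering regulators rose in 22 of 75 and fell in 2 (adjusted p = 0.012, 0.52 with an estimated correlation).

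Phenylpropanoid, flavonoid and stress genes were lower on BAR at 4 week. Of 25 general phenylpropanoid enzymes 13 fell and 5 rose (adjusted p = 0.0013, adjusted p = 0.51 with an estimated correlation). A 4-coumarate-CoA ligase 2 (DVH24_022284) fell from 299 ± 28 to 31.7 ± 12.3 CPM, and phenylalanine ammonia-lyase 1 (DVH24_023938), the entry enzyme of the pathway, from 101 ± 46.3 to 22 ± 8.55 CPM. Of 44 flavonoid genes 17 fell and 5 rose (adjusted p = 0.0096, adjusted p = 0.61 with an estimated correlation), and the anthocyanidin reductase family moved both ways, DVH24_017075 from 390 ± 75.6 to 67.8 ± 33.2 CPM and DVH24_008217 from 14.8 ± 2.04 to 68.4 ± 13.3 CPM. Heat shock genes fell in 35 of 90 cases and rose in 7 (adjusted p = 1.7e-06, adjusted p = 0.51 with an estimated correlation), an 18.5 kDa class I protein (DVH24_023011) from 186 ± 41 to 12.8 ± 2.57 CPM. Calvin cycle genes rose in 12 of 27 cases and fell in 3 (adjusted p = 0.027, adjusted p = 0.65 with an estimated correlation, and adjusted p = 0.082 without the library labelled TDZ, 4 week, replicate 3), sedoheptulose-1,7-bisphosphatase (DVH24_021870) from 44.6 ± 10.7 to 156 ± 13.4 CPM. Large falls were seen in 2 thaumatin-like protein 1a genes (DVH24_035284 and DVH24_035288), of a pathogenesis-related family, from 11200 ± 6620 and 8680 ± 5140 CPM to 4.68 ± 3.35 and 3.28 ± 1.85 CPM. A crocetin glucosyltransferase (DVH24_025655), which adds sugar to a carotenoid product, fell from 220 ± 190 CPM to no count, at least 3940-fold lower, a call lost by limma-voom and in the 4 week libraries alone. These falls were not particular to BAR. In the libraries labelled TDZ, 4 week, replicates 1, 2 and 3, DVH24_035284 stood at 6.33, 4.16 and 13500 CPM. DVH24_035288 stood there at 6.19, 3.53 and 14300 CPM and DVH24_025655 at 0, 0.042 and 99 CPM. On BAR, against no count in the controls, LTL1 (DVH24_036863) stood at least 527-fold higher at 33.3 ± 12.3 CPM, epidermal patterning factor-like 9 (DVH24_028509), which promotes stomata formation, at least 280-fold at 17.7 ± 5.6 CPM, and Cyclin-U4-1 (DVH24_025870) at least 199-fold at 12.6 ± 1.62 CPM. All had counts in the 48 hour controls, at 256 ± 55.6, 11.9 ± 4.42 and 4.9 ± 2.42 CPM. On BAR at 48 hour they stood at 210 ± 48, 10.7 ± 5.09 and 5.16 ± 1.91 CPM, so LTL1 was lower on BAR at 4 week than at 48 hour. In all 4481 genes rose and 3319 fell, with the median gene at 0.14. By limma-voom the calls of LTL1 (DVH24_036863) and of the thaumatin-like gene DVH24_035288 were lost. The total of 7800 was 4824 and 4820 without control, 4 week, replicates 2 and 3, 5012 without BAR, 4 week, replicate 1, and 4335 in the 4 week libraries alone. In that fit 0 type-A regulators, 9 Aux/IAA proteins, 6 SAUR proteins, 12 expansins and xyloglucan enzymes and 6 Calvin cycle genes rose, and 5 flavonoid genes fell.

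**Figure D3:**
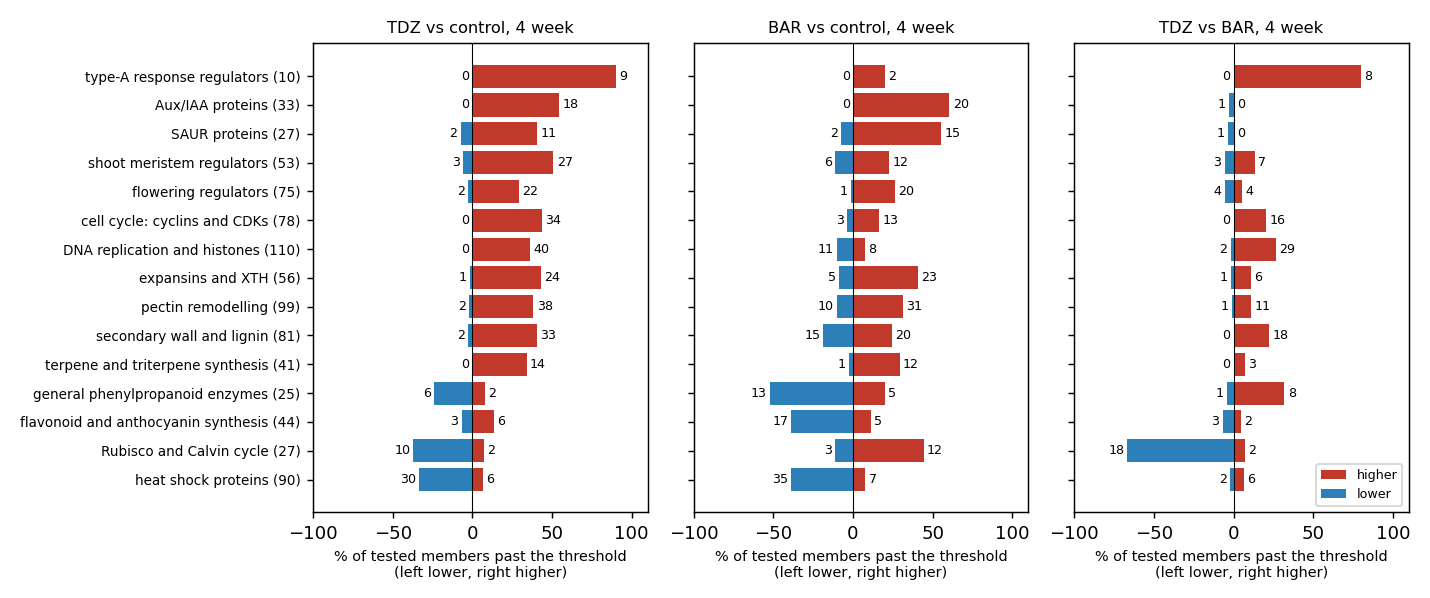
Share of the tested members of 15 gene lists that passed the threshold at 4 week, for TDZ against control, BAR against control and TDZ against BAR; bars to the right are higher genes and bars to the left lower genes, with the number of genes at each bar and the number tested beside each list. Type-A response regulators rose in 9 of 10 cases on TDZ and 2 of 10 on BAR, and general phenylpropanoid enzymes fell in 13 of 25 cases on BAR.

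TDZ and BAR gave many calls in common at 4 week. Of the genes called against the control 2573 were higher on both, 1537 lower on both and 17 went opposite ways, where independent lists of these sizes would share 754.7 and 322.6. The fold changes correlated at 0.77 across genes with a covariance of 2.92, while simulated unchanged groups gave 0.51 and 0.26. In the simulation all groups, controls included, were drawn anew around the control means. It did not carry over the real differences among the control libraries, so it cannot show how much these add. Part of the excess may come from the shared controls, which are too few to split. At 48 hour the correlation was 0.35 and the covariance 0.22, against 0.50 and 0.25 in simulation, and edgeR called 0 genes in each comparison. The 4110 shared genes at 4 week became 6852 without the library labelled TDZ, 4 week, replicate 3, 1902 and 1908 without control replicates 2 and 3, 2221 and 2260 without TDZ replicates 1 and 2, and 938 in the 4 week libraries alone.

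Set against BAR directly, TDZ at 4 week kept cytokinin genes and replication genes higher and photosynthetic carbon fixation lower. Of the 10 type-A regulators 8 were higher and 0 lower (9 and 0 adjusted over the list alone; list adjusted p = 3.6e-06, adjusted p = 0.35 with an estimated correlation), ARR3 (DVH24_007079) at 75.8 ± 66 against 6.33 ± 0.384 CPM. Of the 9 oxidases 5 were higher (6 adjusted over the list alone; adjusted p = 0.00033, adjusted p = 0.091 with an estimated correlation), with cytokinin dehydrogenase 5 (DVH24_020176) at 9.39 ± 1.3 against 0.66 ± 0.37 CPM, a log2 difference of 3.81. Cytokinin dehydrogenase 7 (DVH24_020512) averaged 29.4 ± 2.9 and 28 ± 9.38 CPM, a difference of 0.07 with an interval from -0.55 to 0.68. DNA replication and histone genes were higher in 29 of 110 cases and lower in 2 (adjusted p = 1e-10, adjusted p = 0.33 with an estimated correlation), such as histone H3.2 (DVH24_041965) at 27.9 ± 7.47 against 1.67 ± 1.11 CPM and DNA polymerase epsilon (DVH24_039040) at 19.9 ± 6.96 against 2.06 ± 1.1 CPM. Calvin cycle genes were lower in 18 of 27 cases and higher in 2 (adjusted p = 1.3e-13, adjusted p = 0.091 with an estimated correlation). The genes DVH24_032941 and DVH24_038602, which match Rubisco activase, the chaperone that keeps the carbon-fixing enzyme active, averaged 718 ± 52.5 and 666 ± 209 CPM on TDZ and 3950 ± 1120 and 3990 ± 918 CPM on BAR. Light harvesting and photosystem genes were lower in 18 of 80 cases and higher in 1 (adjusted p = 2.2e-08, adjusted p = 0.51 with an estimated correlation). Without the library labelled TDZ, 4 week, replicate 3, some lists passed with the estimated correlation. The camera adjusted p was then 0.00036 for type-A regulators, 0.043 for oxidases and 0.012 for DNA replication and histone genes. It stayed at 0.18 for Calvin cycle and 0.6 for light harvesting and photosystem genes. General phenylpropanoid enzymes were higher in 8 of 25 cases and lower in 1 (adjusted p = 0.0018, adjusted p = 0.35 with an estimated correlation, and adjusted p = 0.065 without the library labelled TDZ, 4 week, replicate 3), trans-cinnamate 4-monooxygenase (DVH24_038338) at 24.4 ± 12.4 against 0.793 ± 0.498 CPM. Beta-glucosidase 12 (DVH24_038480) was lower on TDZ, at 15.2 ± 3.87 against 222 ± 76.3 CPM.

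TDZ and BAR differed in 1152 higher and 1037 lower genes at 4 week, 2189 in all. This count was 4136 without the library labelled TDZ, 4 week, replicate 3, 1005 without replicate 1 of TDZ, and 198 and 466 without replicates 1 and 3 of BAR. DESeq2 called 2337 higher and 1401 lower genes, limma-voom 463 and 1258, the 4 week libraries alone 51 and 84, and a fit of the 6 libraries compared 0. In the 4 week libraries alone 0 of the 10 type-A regulators and 1 of the 9 oxidases were higher, 2 of 110 DNA replication and histone genes were higher, and 2 of 27 Calvin cycle genes and 0 of 80 light harvesting and photosystem genes were lower. The lists still passed there, with adjusted p = 0.00028 for type-A regulators (adjusted p = 0.61 with an estimated correlation) and 3.9e-14 for the Calvin cycle (adjusted p = 0.23 with an estimated correlation). Of 46 called genes followed in this comparison 30 lost the call without BAR replicate 1, 34 in the 4 week libraries alone and 18 by limma-voom. Acidic endochitinase (DVH24_022468) had a log2 difference of 8.81, which was 1.64 and not called without the library labelled TDZ, 4 week, replicate 3.

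In the control explants growth genes and nuclear photosynthesis genes fell and stress and senescence genes rose between 48 hour and 4 week. DNA replication and histone genes fell in 66 of 110 cases and rose in 2 (adjusted p = 1.1e-12, adjusted p = 0.5 with an estimated correlation), histone H1.1 (DVH24_021763) from 409 ± 66.6 to 71.6 ± 26.1 CPM. Light harvesting and photosystem genes fell in 41 of 80 cases and rose in 0 (adjusted p = 3e-07, adjusted p = 0.6 with an estimated correlation), chlorophyll-binding protein CP26 (DVH24_009559) from 651 ± 87.3 to 184 ± 94.3 CPM. All that fell are among the 66 nuclear members, which had a median of -1.39. The plastid-encoded genes, 41 in all, had a median of -0.15, with 1 lower and 0 higher. Chlorophyll synthesis genes fell in 13 of 22 cases and rose in 1 (adjusted p = 0.0017, adjusted p = 0.6 with an estimated correlation), magnesium chelatase subunit ChlH (DVH24_005011) from 1170 ± 229 to 318 ± 107 CPM. Cuticle and epidermis genes fell in 39 of 69 cases and rose in 9 (adjusted p = 0.00018, adjusted p = 0.5 with an estimated correlation), protodermal factor 1 (DVH24_032695), an epidermal marker, from 220 ± 81.9 to 0.0265 ± 0.0459 CPM. SAUR proteins fell in 15 of 27 cases and rose in 5 (adjusted p = 0.0032, adjusted p = 0.5 with an estimated correlation). Root markers fell in 11 of 18 and rose in 0 (adjusted p = 0.0079, adjusted p = 0.5 with an estimated correlation), SCARECROW (DVH24_036412) from 76.9 ± 39.3 to 0.182 ± 0.135 CPM. Type-A regulators fell in 7 of 10 cases (8 adjusted over the list alone; adjusted p = 0.002, adjusted p = 0.6 with an estimated correlation), ARR6 (DVH24_008781) from 32.3 ± 8.03 to 0.559 ± 0.49 CPM. Of the 9 cytokinin oxidases 1 rose and 3 fell (2 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.55, adjusted p = 0.74 with an estimated correlation). Cytokinin dehydrogenase 7 (DVH24_020512) rose from 18.8 ± 3.03 to 65.6 ± 19.7 CPM. LTL1 (DVH24_036863) fell from 256 ± 55.6 CPM to no count, at least 4050-fold lower, and gibberellin-regulated protein 6 (DVH24_037114) from 112 ± 14.1 CPM to no count, at least 1780-fold lower.

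Heat shock genes rose in 34 of 90 cases and fell in 6 in the control over time (adjusted p = 5.9e-05, adjusted p = 0.5 with an estimated correlation), heat stress factor A-4b (DVH24_031112) from 13.5 ± 2.79 to 69.2 ± 21.6 CPM. WRKY factors rose in 29 of 86 cases and fell in 7 (adjusted p = 0.00018, adjusted p = 0.5 with an estimated correlation), WRKY40 (DVH24_000037) from 10.8 ± 1.77 to 82.1 ± 8.99 CPM. Of 16 senescence markers 5 rose and 1 fell (adjusted p = 0.03, adjusted p = 0.5 with an estimated correlation). Pheophorbide a oxygenase (DVH24_005817), which opens the chlorophyll ring, rose from 116 ± 8.91 to 677 ± 226 CPM, and a STAY-GREEN homolog (DVH24_001298), which starts chlorophyll breakdown, from 6.82 ± 3.62 to 129 ± 97.6 CPM. The genes often taken as constant references moved as well, 10 of 57 higher and 23 lower, a tubulin alpha chain (DVH24_007755) from 977 ± 228 to 53.1 ± 4.5 CPM and a polyubiquitin (DVH24_004610) from 306 ± 75.6 to 1260 ± 84.9 CPM. In all 4083 genes rose and 5469 fell. By limma-voom the calls of ARR6 (DVH24_008781), protodermal factor 1 (DVH24_032695), SCARECROW (DVH24_036412) and LTL1 (DVH24_036863) were lost, with their direction kept. Leaving out each library in turn gave totals from 6612 to 11047.

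Whether the response changed with time was tested as an interaction, the effect at 4 week minus that at 48 hour. A gene that fell in the control between the times can have a higher interaction without a rise on the cytokinin. For TDZ the interaction was higher for 1418 genes and lower for 558. Pectin remodelling genes were higher in 22 of 99 cases and lower in 0 (adjusted p = 1.6e-08, adjusted p = 0.31 with an estimated correlation). Expansins and xyloglucan enzymes were so in 14 of 56 and 0 (adjusted p = 1.4e-06, adjusted p = 0.27 with an estimated correlation). Shoot meristem regulators were so in 13 of 53 and 1 (adjusted p = 3e-05, adjusted p = 0.43 with an estimated correlation). Cuticle and epidermis markers were so in 10 of 69 and 0 (adjusted p = 0.0091, adjusted p = 0.49 with an estimated correlation), and phloem markers in 4 of 31 and 0 (adjusted p = 0.044, adjusted p = 0.43 with an estimated correlation). Without the library labelled TDZ, 4 week, replicate 3, 41 pectin, 28 cuticle and 12 phloem genes were higher and 3, 4 and 2 lower. The camera adjusted p with the estimated correlation was then 0.041, 0.016 and 0.044. It was 0.11 for expansins and xyloglucan enzymes and 0.078 for shoot meristem regulators. Other lists were lower as groups. Light harvesting and photosystem genes had a median of -0.83, 5 of 80 lower and 0 higher (adjusted p = 1.6e-08, adjusted p = 0.43 with an estimated correlation), but the 5 are plastid-encoded, and of the 66 nuclear members 0 were called, with a median of -0.61. Heat shock genes had a median of -0.75, 5 of 90 lower and 2 higher (adjusted p = 1.4e-05, adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes had a median of -0.32 (adjusted p = 7.8e-07, adjusted p = 0.57 with an estimated correlation), chlorophyll synthesis genes -0.44 (adjusted p = 0.0041, adjusted p = 0.54 with an estimated correlation) and circadian clock genes -0.29 (adjusted p = 0.015, adjusted p = 0.43 with an estimated correlation). Expansin-A6 (DVH24_038635) had an interaction of 4.42 (adjusted p = 0.019). The total of 1976 was 7103 without the library labelled TDZ, 4 week, replicate 3, and 4666 without control, 4 week, replicate 1. It was 0, 1, 2 and 1 without TDZ, 4 week, replicates 1 and 2, and control, 4 week, replicates 2 and 3, and 77 and 0 without TDZ, 48 hour, replicates 1 and 2. It was 424, 629 and 82 without control, 48 hour, replicates 1, 2 and 3, 1262 without BAR, 48 hour, replicate 2, and 1279 and 1311 without BAR, 4 week, replicates 1 and 3. DESeq2 called 2999 higher and 1242 lower genes, limma-voom 19 and 53, and a fit of the 12 libraries of TDZ and control 0, with 7016 genes at an unadjusted p under 0.05 in the fit of all 18. None of the 13 called genes followed here, Expansin-A6 included, kept its call in every one of these fits.

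For BAR the interaction was higher for 1746 genes and lower for 1222. Heat shock genes were lower in 20 of 90 cases and higher in 0 (adjusted p = 2.5e-07, adjusted p = 0.32 with an estimated correlation), and the 18.5 kDa class I protein (DVH24_023011) had an interaction of -3.98 (adjusted p = 0.0066). General phenylpropanoid enzymes were lower in 9 of 25 cases and higher in 4 (adjusted p = 0.0014, adjusted p = 0.39 with an estimated correlation). Aux/IAA proteins were higher in 9 of 33 and lower in 0 (adjusted p = 1.8e-06, adjusted p = 0.48 with an estimated correlation). Cytokinin oxidases were lower in 3 of 9 (4 adjusted over the list alone) and higher in 0 (adjusted p = 0.0099, adjusted p = 0.32 with an estimated correlation). The total of 2968 was 5892 without the library labelled TDZ, 4 week, replicate 3, and 5246, 1118 and 1176 without control, 4 week, replicates 1, 2 and 3. It was 1100, 1403 and 1911 without control, 48 hour, replicates 1, 2 and 3, 1240 and 1281 without BAR, 48 hour, replicates 1 and 2, and 1077 and 1323 without BAR, 4 week, replicates 1 and 3. DESeq2 called 2672 higher and 2376 lower genes.

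Plastid-encoded transcripts varied between libraries as well as between groups. Their summed level was 3460, 2600 and 2670 CPM in the 48 hour controls, 3450, 2490 and 3390 CPM on TDZ and 525, 818 and 1650 CPM on BAR. At 4 week it was 297, 4860 and 3980 CPM in the controls, 125, 98.1 and 161 CPM on TDZ and 141, 139 and 125 CPM on BAR. Of the 41 genes 28 fell on TDZ and 29 on BAR at 4 week, and 0 rose. In the 4 week libraries alone 16 fell on TDZ and 24 on BAR, and without the library labelled TDZ, 4 week, replicate 3, 27 fell on TDZ, and 31 fell and 1 rose on BAR. Of 4 mitochondrion-encoded genes other than ribosomal proteins, 3 fell and 1 rose on TDZ, with a median log2 fold change of -3.47, and 3 fell and 0 rose on BAR, with a median of -4.64. These 4 were picked after the values were seen, and the whole list of 8 mitochondrion-encoded genes had medians of -0.07 on TDZ, with 2 higher and 3 lower, and -0.14 on BAR, with 1 higher and 3 lower. Without the library labelled TDZ, 4 week, replicate 3, from the fit, 2 of the 4 fell and 1 rose on TDZ, and 3 fell and 1 rose on BAR. Of the whole list of 8, 3 fell and 2 rose on TDZ in that fit, and 3 fell and 2 rose on BAR. Whether RNA without a poly(A) tail was carried over in different amounts was not tested at 4 week. The fall of plastid-encoded transcripts there may therefore not be a change in expression.

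**Figure D4:**
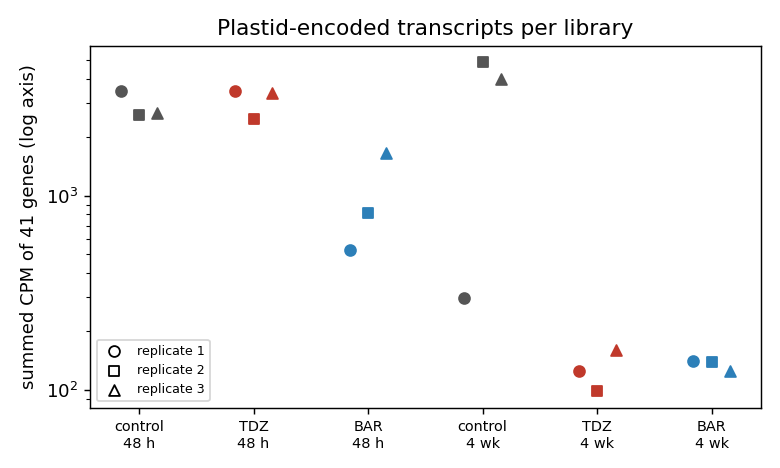
Summed CPM of 41 plastid-encoded genes in each of the 18 libraries on a log axis; colour gives the medium and symbol shape the replicate. The 6 TDZ and BAR libraries of 4 week lie between 98.1 and 161 CPM, and the controls of 4 week at 297, 4860 and 3980 CPM.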

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

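The tests in this part other than that of the whole mitochondrial list were chosen after the result was seen. The change of the TDZ response between 48 hour and 4 week stood out because 1976 genes passed the test of the difference itself, and that of the BAR response because 2968 genes did. Of 30 splits of the same libraries, the real one and 29 drawn at random, 4 gave as many genes for TDZ, with up to 3864 in another split, and 3 for BAR, with up to 5035, so chance is not excluded by these counts. The other splits that gave as many for BAR kept the real groups of 4 week and regrouped only the libraries of 48 hour, so they carry the difference between media at 4 week and say little about random groups. For TDZ 1 of them did so too, and the others differed from the real groups of 4 week only by exchanging the library labelled TDZ, 4 week, replicate 3, with control replicate 1.

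The library labelled TDZ, 4 week, replicate 3, lies far from replicates 1 and 2. None of the 6 control and BAR libraries of 4 week had more than 0.161 CPM of cytokinin dehydrogenase 3 (DVH24_029452), against 212 and 182 CPM in TDZ replicates 1 and 2. So none of them is an exchanged library with the response of those replicates. An exchange with explants on TDZ that gave no such response cannot be told by this gene. A wrong label could explain the median log2 ratio to the controls of 0.08 over the type-A regulators, and explants on TDZ that gave no cytokinin response could equally explain the value of 0.08. Its summed plastid-encoded level of 161 CPM lies near that of the other TDZ and BAR libraries of 4 week (98.1 to 141 CPM) and below the controls (297, 4860 and 3980 CPM), as its label says, and 33 genes stood at 20 CPM or more and over 4 times the highest of the other 17 libraries, such as a Fra a 1-3 allergen gene (DVH24_025442) at 3510 CPM against at most 203 CPM elsewhere. The same count was 17 and 1 in TDZ replicates 1 and 2, and 0 to 2 in the control and BAR libraries of 4 week. These values do not decide between the open explanations.

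Plastid-encoded transcripts were low on BAR at 48 hour. The nuclear photosynthesis genes showed no fall of the plastid size. The 66 nuclear members of the light harvesting list had a median log2 fold change of -0.07 with quartiles from -0.19 to 0.03, and 44 of them were negative. This argues against an equal fall of photosynthesis genes as a whole. The criterion was set after the result was seen, and a small fall of the nuclear genes is not excluded. Different carry-over of RNA without a poly(A) tail could lower organelle transcripts together. The mitochondrion-encoded list had a median of -0.12, on the side set beforehand as against this explanation. Its members went both ways, and its ribosomal proteins may be nuclear genes, so the test cannot decide. Without the ribosomal proteins the median over 4 genes was -1.55, all negative, near the plastid median of -1.64, which goes with carry-over. These 4 were picked after the values were seen, and 1 of them (DVH24_022449) had at most 2.64 CPM at 48 hour. Carry-over therefore stays open, and a biological change in plastid transcription was not tested.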

How the results depend on the processing

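The fit of the libraries of the same time and the list tests without the library labelled TDZ, 4 week, replicate 3, were chosen after the results were seen; the cause of each change was not tested, except that the fits of fewer libraries test fewer samples. Of 9366 values of named genes under the alternatives 8667 kept direction and side of the threshold, 538 lost a call, 152 gained one and 9 turned direction. Limma-voom lost 95, the fit of only the groups compared 115 and the same-time fit 58. Of 53 called genes of BAR against control at 4 week 39 kept the call throughout, and of 63 for the controls over time 44 did. The smallest library held 12546489 counts, where 3 counts make 0.239 CPM.

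At 48 hour TDZ against control gave 0 genes, and 103 by DESeq2, 98 in the groups compared alone, 3 with the libraries ending in b summed, 91 in the same-time fit, and 0 to 25 with 1 library left out. BAR against control gave 5 by DESeq2, 13 in the groups compared and 9 in the same-time fit, and 0 to 1 with 1 left out. TDZ against BAR gave 151, 20 and 29, and 0 to 5. At 4 week TDZ against control gave 4571 by limma-voom, 0 in the groups compared, 1458 in the same-time fit and 3373 to 10828 with 1 left out. BAR against control gave 4335 in the same-time fit and 4820 to 9741 with 1 left out. TDZ against BAR gave 3738 by DESeq2, 0 in the groups compared, 135 in the same-time fit and 198 to 4136 with 1 left out. The controls over time gave 6612 to 11047.

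The TDZ interaction gave 4241 by DESeq2, 72 by limma-voom, 0 in the groups compared, 3460 with the b libraries summed and 0 to 7103 with 1 library left out. The BAR interaction gave 5048 by DESeq2, 5550 in the groups compared and 1077 to 5892. Of 128 list calls 1 was kept with the estimated correlation, and without the library labelled TDZ, 4 week, replicate 3, there were 148 with the preset one. Without that library some lists also passed with the estimated correlation. The camera adjusted p of type-A regulators was then 0.0046 for TDZ and 0.43 for BAR against control at 4 week. For Aux/IAA proteins it was 0.15 and 0.21. Shared calls were 0 in the groups compared, 938 in the same-time fit and 1902 to 6852 with 1 left out.

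With the replicate number as a block (replicate block) TDZ against BAR at 4 week gave 1110 genes, the TDZ interaction 131, the BAR interaction 2121, TDZ and BAR against control at 4 week 5634 and 7052, each comparison at 48 hour 0, the lists 114 and the shared calls 3502. The numbers do not pair the samples: 1 of 9 same-number pairs at 48 hour and 2 of 9 at 4 week correlated over 0.1, and 2 of 9 and 4 of 9 libraries correlated best with their own number.

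Uncalled values that turned direction were those of cytokinin dehydrogenase 7 (DVH24_020512): -0.13 for TDZ at 48 hour without TDZ replicate 1, -0.05 for BAR at 48 hour without BAR replicate 2, 0.11, 0.07 and 0.20 for TDZ against BAR at 48 hour without TDZ replicates 2 and 3 and BAR replicate 2, and at 4 week -0.03 and -0.10 without BAR replicates 1 and 3 and -0.09 with the b libraries summed. ARR3 (DVH24_007079) turned to -0.03 for BAR at 4 week without control replicate 3. With 1 library left out, the highest value of cytokinin dehydrogenase 7 was 0.29 for TDZ and 0.31 for BAR at 48 hour and 0.37 for TDZ against BAR at 4 week, the lowest was -0.31 for TDZ against BAR at 48 hour, and the highest of ARR3 was 0.57.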

Other observations

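The splits in this part were chosen after the results were seen. Dividing the 6 libraries of each comparison into 3 and 3 in all 10 ways leaves too few splits for a share under 0.05. At 48 hour all 10 splits gave as many genes as the real grouping for TDZ against control, for BAR against control and for TDZ against BAR, since each split gave 0. At 4 week 1 of 10 splits gave as many as the real grouping for BAR against control, the real one itself, and the highest other split gave 0. For TDZ against BAR it was 1 of 10, with 574 in the highest other split, and for the controls over time 1 of 10, with 0. For TDZ against control it was 2 of 10, and the split that put control replicate 1 with TDZ replicates 1 and 2, and the library labelled TDZ, 4 week, replicate 3, with the other controls, gave 7499 genes against 6920.

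In the library labelled TDZ, 4 week, replicate 3, a 2-methylene-furan-3-one reductase gene (DVH24_031783) stood at 4280 CPM and jasmonate-induced oxygenase 2 (DVH24_023747) at 2450 CPM. Over 43 glutathione transferases the median log2 ratio to the 4 week controls was 0.24, -0.07 and 0.68 in TDZ replicates 1, 2 and 3, and over 90 heat shock genes it was -0.94, -0.80 and -0.19. In control, 4 week, replicate 1, photosystem II D2 (DVH24_034793) stood at 39.9 CPM, against 1970 and 1590 CPM in control replicates 2 and 3.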
